A study of Mus musculus with 6 samples.

How the data were processed

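Total RNA of 6 libraries of the mouse liposarcoma line mLPS1, 3 labelled wild type and 3 labelled NICD knockout, was extracted with TRI Reagent and sequenced, per the labels' protocols. Groups were taken from the genotype label of each library. The labels call the altered line a knockout, while the series title speaks of over-expression of Notch. The direction of every fold change here, knockout over wild type, is taken from the name the authors gave their table, and nothing else in the sources states it or says which libraries entered.

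The submitters' processing notes name Salmon, DESeq2 and the genome build mm39, with no versions, order or settings, and filters on low counts are not given in the sources used here. Per the file headers, the authors deposited 1 row per gene with the mean over libraries of counts divided by size factors, treated here as a signal that is never negative. They deposited a log2 fold change between the groups with its standard error, also on the log2 scale, per the file headers. The Wald statistic, a score, is the log2 fold change divided by its standard error, and the deposited p-value and its adjusted form follow from it, per the file headers. Recomputing the Wald statistic, the p-value and the Benjamini-Hochberg adjustment from the deposited columns gave differences of at most 1.56e-13, so the adjustment covers every gene with a p in the table. Of 14472 rows, 2 have no p. Because values of single libraries were not used here, no test of group differences was fitted for this work: the calls are those of the authors' DESeq2 table at an adjusted p under 0.05, as fixed for this case before the data were examined. The edgeR test planned for counts was not run.

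From the deposited values, 95% Wald intervals were computed as the log2 fold change plus or minus 1.96 standard errors. A fitted level per group was derived from the mean and the fold change on the assumption that 3 libraries per group entered. Where a group's fitted level lay below 1 normalised count per library (3 counts over the group), the fold change was also computed with that group at this floor: 418 called genes were concerned, 124 below it in the knockout and 294 in wild type. Genes named are the 4 Notch receptors and all tested Notch targets, the 12 steepest rises and 12 steepest falls among genes past the threshold in the upper range of expression (mean of at least 170.7) with a symbol that is not a predicted-gene name, and up to 4 members with the smallest p in each list, 158 genes in all, of which some are not reported here. For 10 symbols that stand on 2 rows, the row with the higher mean was used.

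A set of 31 gene lists was fixed before the data were examined, by name only. For each list the median log2 fold change of its tested members was set against the medians of 10000 random lists of the same size, drawn with the same number of genes in each of 20 expression bins, giving a two-sided p adjusted over the 31 lists by Benjamini-Hochberg. This draw of random lists is what permutation of list members stands for below, and no library labels were permuted. Random lists treat genes as independent, and neither camera with a correlation estimated from the libraries nor fry could be run without values of single libraries. Adjusted over the list alone, the counts of members higher and lower were the same as over all genes for 20 lists, and the other 11 are given beside their counts. Camera on the deposited Wald statistics with a preset correlation of 0.01, and its rank-based form, were run in limma 3.58.1 (R 4.3.3) as alternatives.

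Chromosome and gene order came from the GENCODE M21 annotation of GRCm38, matched by Ensembl gene identifier for 14456 rows (99.9%). As the authors' build is mm39, no coordinates are printed and the annotation serves only for chromosome membership and for which genes neighbour each other. For 10296 protein-coding genes with a mean of at least 100, a neighbour median was taken over 10 such genes on each side, and least-squares segments of at least 10 genes were fitted to fold changes limited to 1.5 either way, at a cost of 6 per segment. A segment counted as shifted at a median of at least 0.3 either way. On simulated data, a planted shift of 1 was recovered in 200 of 200 list tests at an unadjusted p under 0.05. Of 1240 tests of unshifted lists, 67 (5.40%) passed it, among 14470 genes. Shifts were planted only in a few lists of at least 10 members, the same ones in every shuffle. Recovery of smaller shifts, or in shorter lists, was therefore not tested. In the segment step on 10296 genes, 12 of 12 planted blocks were recovered, and 1 false block arose in 3 shuffled genomes. The planted blocks were longer, and their shifts larger, than the smallest that counted as shifted, so recovery near those limits was not tested. Both simulations shuffled fold changes over genes, so these rates hold for uncorrelated genes only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

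Alternatives tried were an adjusted p under 0.01, a mean of at least 10 or at least 100, Bonferroni adjustment, centring on the median of expressed genes, subtracting the neighbour median, a Wald test of a change over 2-fold, and leaving out genes with a standard error over 1. Alternatives that need values of single libraries were not run. Depth per library is unknown, and the Wald intervals rest on the deposited standard errors. Each genotype is 1 line, so any other difference between the lines is part of every fold change.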

Results

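RNA was sequenced from mLPS1, a mouse line of dedifferentiated liposarcoma cells, a soft-tissue tumour of the fat lineage. The series holds 6 libraries, 3 labelled wild type and 3 labelled NICD knockout. NICD is the Notch intracellular domain, the fragment of a Notch receptor that is released on activation, enters the nucleus and switches on target genes together with the DNA-binding protein Rbpj. The titles give each library a p number (35, 37 and 40 in wild type, 34, 36 and 39 in the knockout) without saying what it stands for. The labels name 1 cell line per genotype, and nothing in them says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

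The measurements used here are the authors' deposited table of a single comparison, knockout over wild type, with 14472 genes. It gives each gene a mean normalised count over the libraries, a log2 fold change with its standard error (SE) and a p-value, and values of single libraries were not used here. The depth of each library is therefore unknown, and the mean normalised counts sum to 21033526 in the authors' deposited table. Precision followed expression: the median SE of the log2 fold change in the authors' deposited table was 0.16 for the 10479 genes with a mean of at least 100 and 0.77 for the 3991 below it. Levels given below for a group are fitted from that mean and the fold change, and the intervals are 95% Wald intervals.

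The comparison asks how the liposarcoma line labelled as lacking the Notch intracellular domain differs from the wild type line. The series title speaks of Notch over-expression and its design text of dNICD cells, and whether the wild type line carries an introduced Notch fragment is not given in the sources used here. If it does, the fold changes compare cells without that fragment to cells with it. In the authors' deposited table, direct Notch targets such as Heyl and Nrarp and the markers of pericytes and smooth muscle fell in the knockout, and interferon response genes rose. The collagen VI genes Col6a1, Col6a2 and Col6a3 fell and the chemokine gene Ccl5 rose in the authors' deposited table. Over all genes, 7303 of the 14470 with an adjusted p (50.5%) passed 0.05 in the authors' deposited table, 3675 higher and 3628 lower in the knockout. A change of at least 2-fold was reached by 3350 of these in the authors' deposited table, 1941 higher and 1409 lower. A test of whether the change itself exceeds 2-fold kept 1764 genes, and Bonferroni adjustment kept 3175. Blocks of neighbouring genes on several chromosomes shifted together in the authors' deposited table, and 1405 of 10296 expressed protein-coding genes (13.6%) lay in such blocks, so the median of a gene's neighbours is given below beside some of the changes that it moves.

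**Figure D1:**
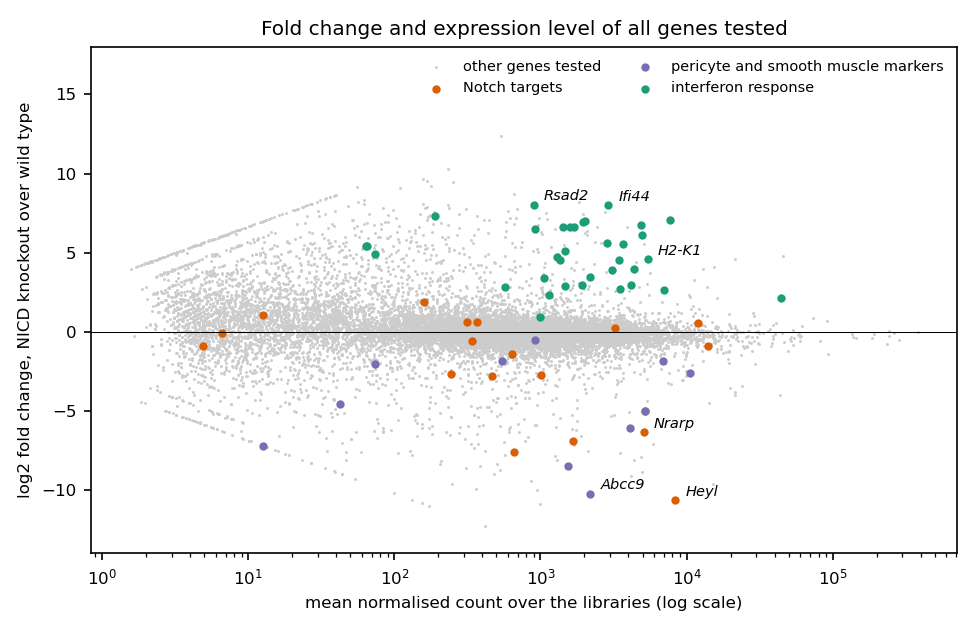
Log2 fold change (knockout over wild type) against the mean normalised count over the libraries (log axis), 1 point per gene of the authors' deposited table, with 3 gene lists in colour; Notch3, in both of the lists with lower medians, is drawn as a pericyte marker. All 35 interferon response genes lie above 0 and all 11 pericyte and smooth muscle markers below it.

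Among the receptors, Notch1 (ENSMUSG00000026923) fell 3.43-fold in the authors' deposited table (log2 fold change -1.78, SE 0.13, adjusted p = 1.08e-38). Notch3 fell 31.8-fold and Notch4 fell 2.43-fold in the authors' deposited table. Notch2 had a log2 fold change of -0.05 (interval -0.34 to 0.24, adjusted p = 0.799). The authors' deposited table holds 1 value per gene, so RNA of an introduced Notch fragment and of the endogenous Notch1 gene are not told apart in it, and the value of Notch1 alone does not check the labels. Of 19 tested Notch targets, 11 fell and 4 rose in the authors' deposited table. Heyl, Hey2 and Hey1, transcriptional repressors that Notch activates directly, had the steepest falls of the list. Heyl (ENSMUSG00000032744) dropped from a fitted level of 16696 to 10.4 in the authors' deposited table (log2 fold change -10.65, SE 1.11, adjusted p = 2.05e-20). Hey2 fell 192-fold, Hey1 fell 119.8-fold and Hes1 fell 6.93-fold in the authors' deposited table. Nrarp, a feedback inhibitor of Notch signalling, fell 79.3-fold in the authors' deposited table (log2 fold change -6.31, SE 0.18, adjusted p = 1.38e-259). Snai2, Dtx1, Sox9, Ccnd1 and Gata2 also fell, with log2 fold changes of -2.74, -2.65, -1.38, -0.91 and -0.58 in the authors' deposited table. The neighbours of Gata2 on chromosome 6 and Ccnd1 on chromosome 7 had medians of -0.57 and -0.35. Gata2 did not pass after its neighbours were subtracted or after centring on expressed genes. Id2, Id1, Gata3 and Cdkn1a rose, with log2 fold changes of 1.91, 0.65, 0.60 and 0.57 in the authors' deposited table. The neighbours of Id2 on chromosome 12 and Id1 on chromosome 2 had medians of -0.81 and -0.34. Myc, Hes2, Hes7 and Il2ra did not pass, with log2 fold changes of 0.21, 1.05, -0.92 and -0.06 in the authors' deposited table.

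The median log2 fold change of the Notch targets was -0.92, below all 10000 random lists of the same size matched on expression (adjusted p = 7.75e-04 over 31 lists, from these permutation draws). Among the 17 targets with a mean of at least 10 the median was -1.38 and among the 16 with a mean of at least 100 it was -2.02. The mean over all 19 was -2.29. Before adjustment the p over all targets is a two-sided 2e-04, the smallest that the random lists can give, and every adjusted p of 7.75e-04 below comes from it. The wider list of Notch pathway components did not pass as a group (median -0.05, adjusted p = 0.907 from random lists by permutation), with 9 of 24 members lower and 6 higher in the authors' deposited table, but passed in camera with a preset correlation (adjusted p = 0.0494, range 0.0494 to 0.907 over 8 alternatives, limma). Within it the ligand Jag1 fell 39.4-fold in the authors' deposited table (log2 fold change -5.30, SE 0.16, adjusted p = 1.38e-224). Numb, an inhibitor of Notch signalling, rose 2.70-fold in the authors' deposited table, where its neighbours on chromosome 12 had a median log2 fold change of 0.95. Rbpj, singled out after its value was seen, rose 2.58-fold in the authors' deposited table, where its neighbours on chromosome 5 had a median of -0.56.

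**Figure D2:**
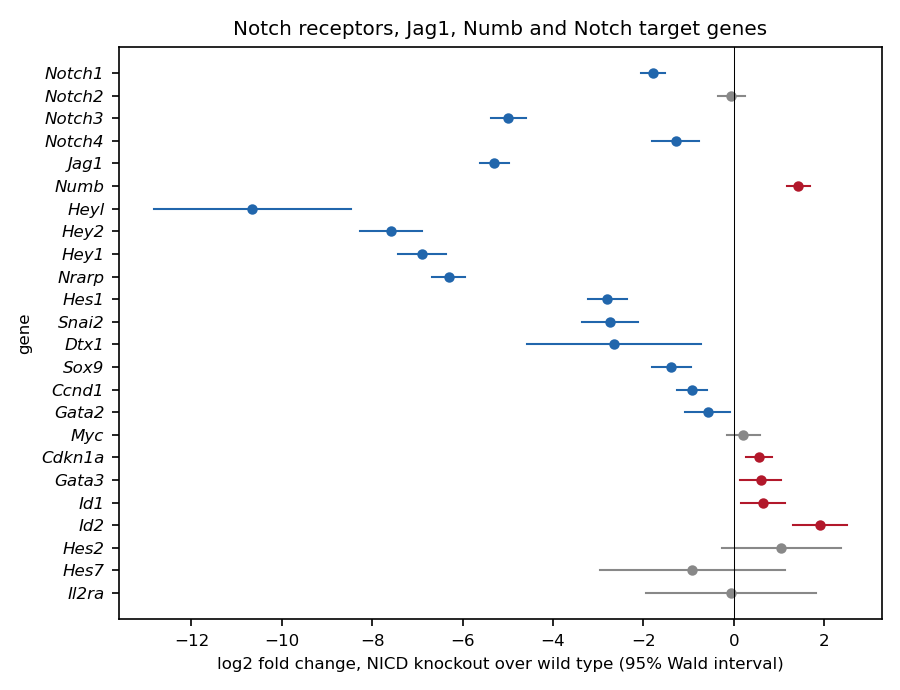
Log2 fold change (knockout over wild type) with its 95% Wald interval for the Notch receptors, Jag1, Numb and the Notch target list in the authors' deposited table; blue genes fell, red genes rose and grey genes did not pass an adjusted p of 0.05. Heyl, Hey2, Hey1, Nrarp, Jag1 and Notch3 lie near or below -5.

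The 12 steepest falls and rises among well expressed genes were named by rule. Besides Heyl, the falls in the authors' deposited table included Ldb2, a cofactor of LIM-domain transcription factors (log2 fold change -10.87, SE 0.74), Abcc9, a subunit of vascular potassium channels (-10.22, SE 0.73) and Tmem178 (-10.18, SE 1.05). The basement membrane collagen gene Col15a1 dropped from a fitted level of 30488 to 38.9 in the authors' deposited table (log2 fold change -9.62, SE 0.59, adjusted p = 2.66e-58). Stc1, which encodes a secreted glycoprotein, and the bile acid receptor gene Gpbar1 fell with log2 fold changes of -9.43 and -9.09 in the authors' deposited table. H2-M9, Pcdhac2, Olfr33 and Clca3b were fitted below 1 normalised count per library in the knockout, and with the knockout set at that floor their log2 fold changes in the authors' deposited table were -9.71, -8.43, -9.50 and -8.95. Olfr78 had a log2 fold change of -9.98 (SE 1.42) in the authors' deposited table, and it, Olfr33, H2-M9, Pcdhac2 and Clca3b belong to gene families that can share reads, so their values are uncertain.

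Among the rises, Bmp4, a growth factor that commits precursors to the fat lineage, and the axon guidance receptor gene Robo2 were fitted below 1 normalised count per library in wild type and at 355.8 and 464.2 in the knockout in the authors' deposited table. With wild type at that floor, their log2 fold changes in the authors' deposited table were 8.48 and 8.86. Brinp3, Pcdh17 and the RNA export factor family member Nxf7 rose with log2 fold changes of 8.01, 7.74 and 7.82 in the authors' deposited table. The other 7 were interferon-inducible genes, Gbp4, Iigp1, Rsad2, Ifi44, Gvin-ps7, Gbp9 and Oas3, with log2 fold changes between 7.57 and 8.74 in the authors' deposited table. Guanylate-binding proteins, immunity-related GTPases, the Gvin pseudogene and Oas genes have close copies that can share reads, so the split of a change among copies is uncertain.

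Interferon response genes were higher as a group. All 35 tested members rose in the authors' deposited table, with a median log2 fold change of 4.93 (30.4-fold), above all 10000 random lists (adjusted p = 7.75e-04 by permutation of list members). Oasl2, an antiviral oligoadenylate synthetase-like gene, rose 69.9-fold in the authors' deposited table (log2 fold change 6.13, SE 0.19, adjusted p = 1.22e-233), and Rtp4 had a log2 fold change of 5.13. Irf7, a transcription factor that amplifies the interferon response, rose 47.2-fold in the authors' deposited table, and the antigen-presenting H2-K1 rose 24.1-fold to a fitted level of 10377. Rsad2 and Ifi44 rose 262.9-fold and 260.6-fold in the authors' deposited table. Secreted inflammatory factors rose too, with 16 of 20 tested members higher and 1 lower in the authors' deposited table (median log2 fold change 3.12, adjusted p = 7.75e-04 by permutation of list members). The chemokine genes Ccl5, Cxcl1 and Ccl2 rose 113.8-fold, 13.9-fold and 7.06-fold in the authors' deposited table. Nfkbia, which encodes the inhibitor that NF-kappaB induces, rose 10.2-fold in the authors' deposited table, where its neighbours on chromosome 12 had a median log2 fold change of 0.82. The 1 member that fell was Il6, at a log2 fold change of -3.51 in the authors' deposited table, named after its value was seen.

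Markers of pericytes and smooth muscle, the contractile cells of vessel walls, were lower as a group. All 11 tested members fell in the authors' deposited table, with a median log2 fold change of -4.55 (adjusted p = 7.75e-04 by permutation of list members), and 1 of them, Notch3, is also in the Notch target list. Abcc9 (ENSMUSG00000030249) fell 1196-fold in the authors' deposited table, from a fitted level of 4390 to 3.67. Mcam, an adhesion molecule of vessel walls, fell 66.5-fold and the proteoglycan gene Cspg4 fell 6.15-fold in the authors' deposited table. Targets and components of TGF-beta and YAP signalling had 11 of 22 members lower and 6 higher in the authors' deposited table (12 lower and 6 higher when adjusted over the list alone), with a median log2 fold change of -0.67 (adjusted p = 0.00138 by permutation of list members). The lower members include the ligand, receptor and mediator genes Tgfb1, Tgfb2, Tgfb3, Tgfbr1 and Smad3, so the list does not measure targets alone. The receptor gene Tgfbr2 and Skil rose with log2 fold changes of 1.71 and 0.85 in the authors' deposited table, and Smad6 and Smad7 did not pass. The contractile genes Tagln and Acta2 fell 134-fold and 15.6-fold in the authors' deposited table, and Tgfb2 fell 5.70-fold. The YAP targets Ccn1, Ccn2, Ankrd1 and Amotl2, singled out after their values were seen, rose with log2 fold changes of 0.79, 0.68, 0.78 and 0.72 in the authors' deposited table. The neighbours of Ccn1 and Ankrd1 had medians of 0.31 and 0.32. Other YAP targets of the list did not rise: Lats2 fell with a log2 fold change of -0.63 in the authors' deposited table, and Axl did not pass at -0.27 (adjusted p = 0.0707). The call for this list was not kept by rank-based camera (adjusted p = 0.0992, range 1.68e-04 to 0.0992 over 8 alternatives, limma).

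Extracellular matrix genes fell as a group, with 18 of 29 lower and 4 higher in the authors' deposited table (19 and 5 when adjusted over the list alone) and a median log2 fold change of -1.26 (adjusted p = 7.75e-04 by permutation of list members). The collagen VI genes Col6a2 and Col6a1 fell 15.6-fold and 13.8-fold in the authors' deposited table (log2 fold changes -3.96, SE 0.19, and -3.78, SE 0.21). Timp3, an inhibitor of matrix proteases, and the collagen cross-linking enzyme gene Loxl2 fell 17.6-fold and 8.35-fold in the authors' deposited table. Matrix proteases and their regulators had 12 of 22 members lower and 4 higher in the authors' deposited table, with a median of -0.66 (adjusted p = 7.75e-04 by permutation of list members). Adamts2, which trims procollagens, fell 198-fold in the authors' deposited table, Adamts9 fell 63.0-fold and Adam19 fell with a log2 fold change of -4.17. The median of the protease list lay between -1.12, at a mean of at least 100, and -0.40, without members of other lists. The list did not pass in rank-based camera (adjusted p = 0.0696, range 3.36e-04 to 0.0696 over 8 alternatives, limma). Regulators of epithelial-mesenchymal transition had 12 of 14 members lower and 1 higher in the authors' deposited table, with a median of -0.69 (adjusted p = 0.00558 by permutation of list members). The mesenchymal cadherin gene Cdh11 fell 184-fold, Itgb3 fell 8.38-fold and Zeb2 fell 3.40-fold in the authors' deposited table, while S100a4 rose 3.44-fold.

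**Figure D3:**
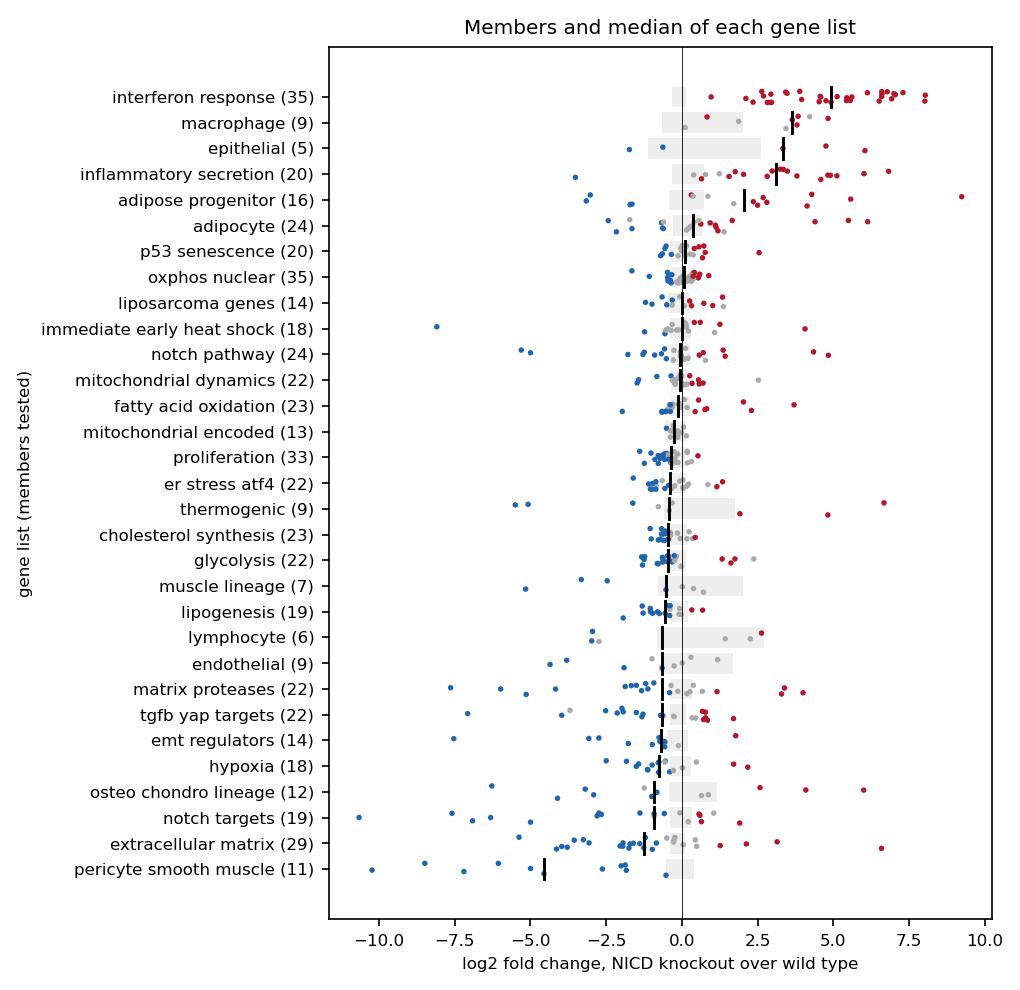
Log2 fold change (knockout over wild type) of each tested member of the 31 gene lists in the authors' deposited table, coloured red or blue where an adjusted p passed 0.05 and grey otherwise; black bars are list medians and grey bands hold 95% of the medians of random lists of the same size matched on expression. The interferon response has the highest median (4.93) and the pericyte and smooth muscle markers the lowest (-4.55).

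Genes of the fat lineage moved in both directions. Markers of adipose progenitors had 9 of 16 members higher and 4 lower in the authors' deposited table (10 and 4 when adjusted over the list alone), with a median log2 fold change of 2.04 (adjusted p = 7.75e-04 by permutation of list members). Ly6a, the Sca-1 antigen of progenitor cells, rose 47.7-fold in the authors' deposited table (log2 fold change 5.58, SE 0.13) and F3 rose with a log2 fold change of 2.81, while the receptor gene Pdgfrb fell 8.11-fold and Wnt5a fell 8.88-fold. The neighbours of Ly6a had a median of 0.71, and its rise alone does not show a change of progenitor state. The progenitor list did not pass in rank-based camera (adjusted p = 0.0960, range 7.71e-04 to 0.0960 over 8 alternatives, limma). The adipocyte list had 9 of 24 members higher and 6 lower in the authors' deposited table (9 and 7 when adjusted over the list alone) and did not pass as a group (median 0.36, adjusted p = 0.474 by permutation of list members). With neighbours subtracted it did not pass either (median 0.76, adjusted p = 0.0570, range 0.0570 to 0.492 over 8 alternatives). Of the 34 genes on the adipocyte list, 10 were not tested, among them Adipoq, Lep and Plin1. Fabp4, a fatty acid carrier of adipocytes, rose 70.3-fold in the authors' deposited table from a fitted level of 4.38 to 307.4. Plin4, a lipid droplet protein gene, and the lipase gene Pnpla2 rose 21.1-fold and 2.29-fold in the authors' deposited table, and the lipoprotein lipase gene Lpl fell 5.38-fold. Pparg, the master regulator of fat cell differentiation, had a mean normalised count of 9.42 and did not pass in the authors' deposited table (log2 fold change -1.72, adjusted p = 0.0542). The thermogenic list had 3 of 9 members higher and 3 lower in the authors' deposited table (3 and 4 when adjusted over the list alone; median -0.41, adjusted p = 0.133 by permutation of list members), and passed only after neighbours were subtracted (median -0.71, adjusted p = 0.0405, range 0.0405 to 0.7502 over 7 alternatives). Of the 20 genes on the thermogenic list, 11 were not tested, among them Ucp1, Prdm16 and Cidea. Dio2 and Ebf2 fell with log2 fold changes of -5.50 and -5.07 in the authors' deposited table, Tnfrsf9 rose 3.78-fold, and Ppargc1a, fitted below 1 normalised count per library in wild type, had a log2 fold change of 4.32 with wild type at that floor.

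Lipid synthesis genes were for the most part lower, by smaller amounts. Fatty acid synthesis and desaturation genes had 12 of 19 members lower and 2 higher in the authors' deposited table (13 and 2 when adjusted over the list alone; median -0.55, adjusted p = 0.0172 by permutation of list members). The desaturase genes Fads2, Scd2 and Fads1 fell 3.82-fold, 2.47-fold and 2.04-fold in the authors' deposited table, and the elongase gene Elovl6 fell 2.06-fold. Genes of fatty acid synthesis itself, singled out after their values were seen, did not all fall. Fasn rose with a log2 fold change of 0.69 in the authors' deposited table, where its neighbours had a median of 0.67. Acaca, Acacb and Acly did not pass. Cholesterol synthesis genes had 14 of 23 members lower and 1 higher in the authors' deposited table (15 and 1 when adjusted over the list alone; median -0.44, adjusted p = 0.0310 by permutation of list members). Dhcr7, an enzyme of the pathway, and Srebf2, a transcription factor that activates it, fell 2.01-fold and 1.71-fold in the authors' deposited table. The cholesterol call was not kept by camera with a preset correlation (adjusted p = 0.158, range 0.00420 to 0.158 over 8 alternatives, limma).

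Hypoxia response genes had 12 of 18 members lower and 2 higher in the authors' deposited table, with a median of -0.76 (adjusted p = 7.75e-04 by permutation of list members). Pdk1, Hif1a, Bnip3 and P4ha1 fell 3.54-fold, 2.83-fold, 2.69-fold and 2.20-fold in the authors' deposited table. Hif1a stands at the start of a block of 36 genes on chromosome 12 with a median of -0.88. Glycolysis genes did not pass as a group (median -0.45, adjusted p = 0.0646 by permutation of list members), with 15 of 22 members lower and 3 higher in the authors' deposited table (15 and 4 when adjusted over the list alone). Tpi1, Pgk1 and the lactate exporter gene Slc16a3 fell 2.46-fold, 2.37-fold and 2.33-fold in the authors' deposited table, the lactate transporter gene Slc16a1 rose 3.08-fold. The neighbours of Tpi1 on chromosome 6 and of Slc16a3 on chromosome 11 had median log2 fold changes of -0.54 and 0.69. After subtracting each gene's neighbours, and in 3 of the other 7 alternatives, the glycolysis list passed (adjusted p from 0.00555 to 0.0678 over all 8). Fatty acid oxidation genes went both ways, 7 of 23 higher and 7 lower in the authors' deposited table (7 and 8 when adjusted over the list alone; median -0.12, mean 0.18, adjusted p = 0.669 by permutation of list members). Pdk4 rose 13.0-fold and Ehhadh rose 4.92-fold in the authors' deposited table, and Acaa2 and Ppard fell 3.90-fold and 1.57-fold. The neighbours of Ppard had a median of -0.24.

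None of the 3 mitochondrial gene lists passed as a group, although single members changed. Nuclear genes of oxidative phosphorylation had 9 of 35 members higher and 9 lower in the authors' deposited table (median 0.08, adjusted p = 0.133 by permutation of list members). Ndufa10 and Atp5c1 fell 3.13-fold and 1.34-fold and Ndufa2 rose 1.85-fold in the authors' deposited table. The neighbours of Ndufa2 on chromosome 18 had a median log2 fold change of 0.51, which left 0.38 of its 0.89. Atp5o fell 2.10-fold in the authors' deposited table, where its neighbours on chromosome 16 had a median log2 fold change of -1.09, and with that median subtracted its value was 0.02. The 13 genes encoded by mitochondrial DNA made up 8.49% of the summed mean counts in the authors' deposited table, and only mt-Nd1 passed among them (log2 fold change -0.51, adjusted p = 0.0258), while 0 passed when adjusted over the list alone (list median -0.24, adjusted p = 0.872 by permutation of list members). Genes of mitochondrial fusion, fission and turnover had 5 of 22 members higher and 4 lower in the authors' deposited table (median -0.06, adjusted p = 0.907 by permutation of list members). Bnip3 fell 2.69-fold and Gabpa fell 2.78-fold in the authors' deposited table, and the neighbours of Gabpa on chromosome 16 had a median log2 fold change of -0.82. Mfn1 rose 1.63-fold and Nrf1 fell 1.77-fold in the authors' deposited table, with neighbour medians of 0.41 and -0.58, and neither passed after that median was subtracted.

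Proliferation genes had 16 of 33 members lower and 1 higher in the authors' deposited table (19 and 1 when adjusted over the list alone). Their median of -0.36 did not pass (adjusted p = 0.0646 by permutation of list members), but it passed in 3 of 8 alternatives, both camera tests among them (adjusted p from 5.66e-04 to 0.0765 over all 8). The cell cycle genes Rrm2, Foxm1, Mki67 and Mcm2 fell 2.62-fold, 2.35-fold, 2.02-fold and 1.85-fold in the authors' deposited table, where the neighbours of Rrm2 on chromosome 12 had a median log2 fold change of -0.79 and those of Foxm1 and Mcm2 on chromosome 6 medians of -0.45 and -0.46. The p53 and senescence list had 6 of 20 members higher and 5 lower in the authors' deposited table (median 0.10, adjusted p = 0.295 by permutation of list members). Trp53, Mdm2 and Plk2 rose 1.71-fold, 1.66-fold and 5.87-fold in the authors' deposited table and Ccng1 fell 1.56-fold. Genes altered in liposarcoma had 5 of 14 members higher and 5 lower in the authors' deposited table (median 0.01, adjusted p = 0.669 by permutation of list members), with Hmga2 up 2.03-fold and Rb1 down 1.98-fold. Genes of the endoplasmic reticulum stress and Atf4 responses had 9 of 22 members lower and 2 higher in the authors' deposited table (median -0.38, adjusted p = 0.133 by permutation of list members), and passed only against random lists not matched on expression (adjusted p = 0.0406, range 0.0406 to 0.603 over 8 alternatives). With neighbours subtracted the median of these stress genes was -0.18. Pdia4, Hspa5 and Sdf2l1 fell 3.04-fold, 1.98-fold and 1.95-fold and Dnajb9 rose 2.23-fold in the authors' deposited table, where the neighbours of Pdia4 on chromosome 6 had a median log2 fold change of -0.78. Immediate early and heat shock genes had 4 of 18 members higher and 3 lower in the authors' deposited table (median 0.002, mean -0.21, adjusted p = 0.847 by permutation of list members). Klf4 rose 16.8-fold and Dusp1 and Nr4a1 fell 2.34-fold and 1.47-fold in the authors' deposited table, and Hspa1a, which can share reads with the near-identical Hspa1b, had a log2 fold change of -5.54 with the knockout at the floor.

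Markers of other cell types were also examined. Macrophage markers had 5 of 9 members higher and none lower in the authors' deposited table, with a median log2 fold change of 3.64 (2.84 with low levels set at the floor and 2.24 among the 4 with a mean of at least 10; adjusted p = 0.00620 by permutation of list members). The members with substantial levels were Cd68 and Cd14, which rose 12.5-fold and 14.0-fold in the authors' deposited table, and Lyz2, which rose 1.78-fold to a fitted level of 157.1. C1qb was fitted at 10.3 in the knockout in the authors' deposited table. Bone and cartilage lineage genes had 6 of 12 members lower and 3 higher in the authors' deposited table (median -0.91, adjusted p = 0.00672 by permutation of list members). Spp1 and Col11a1 rose 17.1-fold and 64.2-fold, Msx2 fell 1.99-fold, and Dlx5 had a log2 fold change of -6.22 with the knockout at the floor in the authors' deposited table. The bone and cartilage call was lost in 4 of 8 alternatives (adjusted p from 0.00507 to 0.742), and the median was 0.65 among members with a mean of at least 100. Epithelial genes had 3 of 5 members higher and 2 lower in the authors' deposited table (median 3.34, adjusted p = 0.0488 by permutation of list members), and this call was lost in 4 of 7 alternatives (adjusted p from 0.00858 to 0.673). The epithelial median was 1.36 among the 4 with a mean of at least 10. Krt8 rose 10.1-fold to a fitted level of 54.4 and Krt14 fell 3.31-fold in the authors' deposited table, and with wild type at the floor Krt19 and Cldn4 had log2 fold changes of 4.65 and 3.69. Endothelial markers did not pass as a group (median -0.65, adjusted p = 0.0803 by permutation of list members), with 4 of 9 lower in the authors' deposited table, but passed in 3 of 8 alternatives (adjusted p from 8.87e-05 to 0.198). The endothelial median was -3.80 among the 3 with a mean of at least 100 and -0.32 with neighbours subtracted. Flt1 and Esam fell 20.4-fold and 13.9-fold in the authors' deposited table, Kdr fell 3.75-fold and Egfl7 fell 1.57-fold. The neighbours of Egfl7 had a median of -0.33, and it did not pass with these subtracted or after centring on expressed genes. Muscle lineage genes had 4 of 7 members lower in the authors' deposited table (median -0.52, adjusted p = 0.159 by permutation of list members), Cdh15, Chrna1, Acta1 and Des, with log2 fold changes of -5.16, -3.32, -2.46 and -0.52. Without members of other lists the muscle median was -1.22 (adjusted p = 0.0550, range 0.0550 to 0.340 over 7 alternatives). Lymphocyte genes had 1 of 6 members higher and 2 lower in the authors' deposited table (median -0.65, adjusted p = 0.129 by permutation of list members). Trac fell and Cd79a rose, with log2 fold changes of -2.94 and 2.63 in the authors' deposited table, and Ms4a1 did not pass at 2.26 (adjusted p = 0.0787).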

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

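All alternatives named here other than the adjusted p of 0.01 and the mean of at least 10 or 100 for gene counts and named genes were chosen after the data were seen. Against 7303 changed genes (3675 higher, 3628 lower) and 3350 changed at least 2-fold, an adjusted p under 0.01, a mean of at least 10, centring, subtracting the neighbour median and leaving out genes with a standard error over 1 gave 5853 to 7293 changed genes. The near-even split is not stable: more genes were higher after centring (3976 to 3317) and with neighbours subtracted (3774 to 3069), and more were lower at a mean of at least 100 (2577 to 3192). A mean of at least 100 left 1839 genes changed at least 2-fold, as fewer genes were tested. The test of a change over 2-fold gave 1764 changed genes (1016 higher, 748 lower) and Bonferroni adjustment 3175 (1516 higher, 1659 lower; 2195 at least 2-fold), both being stricter by construction. Of 158 named genes, 10 were no longer past the threshold at 0.01, 24 with Bonferroni and 48 in the test over 2-fold; with neighbours subtracted, 4 of 154 were lost and Atp5o turned from -1.07 to 0.019, as its neighbours fell with it. Between 12 and 19 of the 31 lists passed in 8 alternatives, against 15, and 9 of the 15 passed in all of them. The bone and cartilage list reversed, to a median of 0.65 among the 5 of 12 members with a mean of at least 100 and to a Wald statistic 1.74 above that of other genes in camera. Neither reversed value passed (adjusted p = 0.0889 from random lists and 0.377 in camera), and rank-based camera kept the lower direction without passing (adjusted p = 0.653). The cause of the reversal was not tested. No paired analysis was possible because values of single libraries were not used here. For the same reason other normalisations, limma-voom, edgeR, thinning, the p number as a covariate, pseudocounts, fry, an estimated correlation and leaving out each library were not run. Depth limits genes of low counts: the median standard error was 1.21 below a mean of 10 and 0.13 from 1000.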

Other observations

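Gene groups in this part were assembled after the data were seen, and so were all tests here except that of chromosome medians. In a group of 18 genes of class I antigen presentation and its regulation, 6 of which are also in the interferon list, all 18 rose in the authors' deposited table (median log2 fold change 3.15), among them Nlrc5, the transactivator of class I genes, at 6.10, and Cd274, which encodes PD-L1, at 4.24. That group left out part of the H2 class I family: of all 15 tested H2-K, D, Q, T and M genes with a number, 10 rose, 3 did not pass the threshold and 2 fell, H2-M9 and H2-M1, with log2 fold changes of -9.71 and -6.45 in the authors' deposited table with the knockout at the floor, and reads can be shared within the family. Of 12 sensors and regulators of nucleic acids in the cytoplasm, 2 of them in the interferon list, 11 rose in the authors' deposited table, including Zbp1 at a log2 fold change of 7.54 and Sting1 at 1.58. The neighbours of Sting1 on chromosome 18 had a median of 0.70. Ifnb1 was the only interferon gene tested, at a mean normalised count of 4.21 and, with wild type at the floor, a log2 fold change of 3.04 in the authors' deposited table (adjusted p = 0.00521). The 18 genes of the interferon list taken as having no close copy are among its 35 members that all rose, so their count is no further test. Their median log2 fold change was 3.93 in the authors' deposited table, against 4.93 for the whole list.

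Genes of cyclic GMP signalling and contraction fell for the most part, as the pericyte markers did: 9 of 11 were lower in the authors' deposited table, with a median of -4.83. The guanylate cyclase subunit genes Gucy1a1 and Gucy1b1 fell with log2 fold changes of -8.47 and -5.64 in the authors' deposited table, Actg2 and Prkg1 with -7.84 and -3.65, while Pde5a rose with 2.41. Integrin genes split in the authors' deposited table, with 13 of 22 lower and 8 higher, from Itga1 at -5.27 to Itgb7 at 6.30 (median -0.69, adjusted p = 0.00133 by permutation of list members). Hox genes, which mark position along the body, showed no common shift in the authors' deposited table, with 8 of 28 higher and 9 lower (median 0.03, adjusted p = 0.848 by permutation of list members). With neighbours subtracted the Hox median was 0.235, which was not tested. Of 34 collagen genes, 11 were higher and 13 lower in the authors' deposited table (median 0.38, above that of random lists, adjusted p = 0.0275 by permutation of list members). No minimum mean was applied to this group. The higher collagens included Col9a3, Col4a3 and Col11a2, with mean counts of 11.6, 26.3 and 29.1, and the largest mean among them was 1235.8 (Col4a5). The lower ones included the abundant Col1a1, Col6a1 and Col4a1, with means of 19458, 21344 and 29268, but also Col28a1 at 4.77. Of 74 ribosomal protein genes, 6 were higher and 36 lower in the authors' deposited table (median -0.26, adjusted p = 0.414 by permutation of list members).

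Fold changes shifted in blocks along the chromosomes. On 6 autosomes the median lay at least 0.2 from that of all autosomal genes, with both quartiles moving the same way. These were 18 (0.52), 11 (0.25) and 3 (0.23) above, and 12 (-0.51), 6 (-0.47) and 16 (-0.29) below. On chromosome 12 the upper quartile hardly moved (0.247, against 0.245 on chromosome 14, which is not among the 6). That chromosome holds blocks shifted either way, so it did not fall as a whole. Each of the 6 had an adjusted p of 5.71e-04 from random draws of autosomal genes. Such draws treat genes as independent, but fold changes of adjacent genes were correlated (r = 0.22), so this p overstates the evidence. Chromosome 2 had the same adjusted p at a shift of only -0.096. Segmentation found 25 breaks within chromosomes against a mean of 0.35 in 20 shuffled orders, with blocks such as Mrpl39 to the end of chromosome 16 (52 genes, median -1.13) and Dcaf4 to Erg28 on chromosome 12 (33 genes, median 1.43), but the blocks at Sp100 on chromosome 1 and Trim34a on chromosome 7 hold clusters of related genes. Removing the trend on GC content and transcript length left each of the 6 medians at least 0.244 away, and leaving out genes changed 2-fold or more left them at least 0.174 away, so neither accounts for the shifts. A gene dosage difference between the 2 lines is a candidate explanation, but the count of 6 autosomes restates the shift, so dosage and other regional causes cannot be told apart without DNA data, and subtracting the neighbours ended the call of 1323 of 5630 called expressed genes and gave a call to 956 others.

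The interferon response may reflect the loss of the Notch fragment or another difference between the lines, and the tests bear on 3 other explanations. With each gene's neighbours subtracted the list median was 5.36 against 4.93, so dosage of the neighbourhood does not account for it. The 4 interferon receptor genes fell, with a median log2 fold change of -1.53, and Ifnar1, Ifnar2 and Ifngr2 lie in the lowered block of chromosome 16, so the receptors give no rise in RNA to explain it. Of the 9 tested macrophage markers, Cd68, Cd14 and Lyz2 stood at 65.9%, 22.6% and 4.63% of the interferon list's median level in the knockout, but the median marker stood at 0.404% and Csf1r at 0.663%, which argues against macrophages as the source of these transcripts and leaves the rise of Cd68 and Cd14 open. What starts the response was not tested.

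The fall of pericyte and smooth muscle markers likewise remained after neighbours were subtracted, at a median of -4.17 against -4.55, which argues against dosage of their neighbourhood. Abcc9 and Kcnj8 both fell although the neighbours of Abcc9 on chromosome 6 had a median log2 fold change of 0.85. A difference between the 2 lines other than Notch cannot be told apart from an effect of Notch, because the labels name 1 cell line per genotype. As a hypothesis, the contractile and vessel-wall genes may depend on Notch in this line, and a further knockout line or restored NICD would test it.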
